A study of Mus musculus with 2 samples.

How the data were processed

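Nuclei came from 2 livers, 1 wild-type and 1 Cox10-/-, that were perfused, digested and strained at 70 µm before nuclear isolation, with 7000 nuclei loaded per sample on a 10x Chromium Next GEM 3' v3.1 kit. Per the submitters' processing notes reads were handled with Cell Ranger 7.0 on mm10. The deposited table holds raw counts, that is UMIs per gene and nucleus, for 32286 genes and both libraries, with no normalization by the authors. Its values run from 601 to 3999 genes per nucleus with mitochondrially encoded UMIs under 20%, so nuclei had been filtered before deposit. Use of intronic reads, the annotation and the authors' filter are not given in the sources used here. Symbols were matched to GENCODE vM21 for coordinates and exon lengths, with 31424 of 32286 found.

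Nuclei with at least 500 UMIs, at least 300 genes and at most 10% mitochondrially encoded UMIs were kept, a limit fixed before the data were examined. It left 1542 wild-type nuclei (28.3%) and 3128 Cox10-/- nuclei (60.5%), since 71.7% and 39.3% of deposited nuclei lay above 10%. Scrublet, run per library at an expected rate of 5%, marked 0 wild-type and 14 Cox10-/- nuclei (0.27%), too few for the call to have worked, and only these were removed. Counts were scaled to 10000 per nucleus and logged, and 2000 variable genes, scaled with a maximum of 10, gave 30 principal components. A graph of 15 neighbours was clustered by the Leiden method at a resolution of 1.0 with seed 1 and no integration of the libraries, which gave 16 clusters.

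Clusters were named from 15 marker lists fixed in advance, merged into hepatocyte, endothelial, stellate, myeloid, lymphoid and cholangiocyte classes. The naming thresholds were set after the data were seen. A non-hepatocyte cluster needed a log2 marker excess of at least 2 for 1 class alone, at least 3 detected markers and a leading gene at least 8-fold above other nuclei. A hepatocyte cluster needed a hepatocyte excess above 0, at least 3 detected markers and an excess under 1 for every other class. Clusters that met neither rule stayed unnamed, at 1.69% of wild-type and 11.4% of Cox10-/- nuclei.

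UMIs were summed over the hepatocyte-like nuclei of each library and divided by the total of the sum to give CPM. Log2 ratios used a prior of 0.5 UMI per library, scaled to library size. Intervals at 95% are exact: Poisson for a sum, Clopper-Pearson for a share and conditional binomial for a ratio. Ranges of list medians and of the marker SD are instead the central 95% of 200 Poisson redraws of the observed counts. These redraws add counting error to counts that already hold it, so a value can lie near an end of its range. A count of 0 was given a floor of 3 counts over the library. Genes with at least 20 UMIs over both sums entered, and a gene counted as at least 2-fold higher or lower when its whole interval also lay beyond 1.5-fold. On counts simulated from the real sums with planted ratios, this rule called 42.0% of genes planted 2-fold higher, 36.0% planted 2-fold lower, 100% planted 4-fold higher, 85.1% planted 4-fold lower and 4 of 11218 unplanted genes. The simulated counts carried Poisson error only, so these rates leave out the spread between animals, nuclei and preparations. With 1 library per group no test of groups was run, since nuclei of 1 animal are not replicates.

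For 40 gene lists fixed in advance, members at least 1.5-fold higher, 1.5-fold lower or between were counted, and the median was ranked among 10000 random lists of the same size drawn within 20 expression bins. An added ranking matched on 10 expression and 10 exon length bins. A gene was called above free RNA when its CPM in hepatocyte-like nuclei was at least 2 times that in the named other nuclei of its library. A gene that other cell types express at a similar level cannot pass, so failing the rule does not mark its signal as free RNA. That reference came from all deposited nuclei, 154 wild-type (443576 UMIs) and 3226 Cox10-/- (8307802 UMIs), since few wild-type ones passed the mitochondrial limit. In the Cox10-/- library it included a cholangiocyte-like cluster of 190 nuclei with Nrg1, Pdk4 and Areg among its leading genes. Named genes were Cox10, the 14 highest and 14 lowest by the interval end nearest to 1 with at least 20 CPM in the higher library, leaving out predicted, mitochondrial and sex chromosome genes, and up to 4 members of each list with the largest ratio. Genes that lead clusters, the checks Mki67 and Top2a, and list members above free RNA were given outside this rule, the last after their values were seen.

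For cycling, each nucleus was thinned to 1000 UMIs and counted when it had at least 2 UMIs over a list. The alternatives fixed in advance were TMM and DESeq2 factors, a library size without mitochondrially encoded genes, at least 1000 genes per nucleus, at most 1% mitochondrially encoded UMIs, no filter beyond the deposited table, doublets kept and Leiden resolutions of 0.5 and 2.0. Also fixed in advance were the mean over nuclei of each nucleus's CPM, thinning of all nuclei to 1000 UMIs, a minimum of 100 UMIs or none, a prior of 5, thinning to 2000 UMIs, no thinning, and at least 1 UMI for cycling. Chosen after seeing the data were leaving out the shallow cluster (hepatocyte-like clusters with Malat1 under 50% of its library level), removing the highest 4% of doublet scores, restricting to genes above free RNA, matching on exon length, classes with at least 30 nuclei, and counting unnamed clusters with markers of 1 other lineage under it. In other classes, lists were read over genes above their level in hepatocyte-like nuclei of the library in which the gene was higher, from 5 such genes, and, chosen after seeing the data, 7 lists also over all measured genes.

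Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.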

Results

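The series holds 2 single-nucleus RNA libraries from regenerating mouse liver, 1 from a wild-type and 1 from a Cox10-/- liver. The mice carried a floxed Cox10 allele and received AAV8-GFP or AAV8-Cre, adeno-associated viruses that mainly infect hepatocytes, 4 weeks before 70% partial hepatectomy, the surgical removal of most of the liver. The treatment protocol places dissection 4 days after surgery, whereas the sample characteristics state 4 weeks, so the stage of regrowth is not settled. Nuclei were profiled by droplet-based 3' sequencing. The wild-type library held 5448 nuclei and 17703804 UMIs (unique molecular identifiers, 1 per captured transcript), with a median of 2853.5 UMIs per nucleus. The Cox10-/- library held 5167 nuclei and 14476400 UMIs, with a median of 2291 UMIs. There were no replicates in either group, so every comparison describes 2 libraries, no test was run, and intervals in parentheses are 95% intervals that cover counting error only.

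The first comparison asked whether the transcript of the targeted gene was lower in hepatocytes of the Cox10-/- library. Cox10 encodes the farnesyltransferase that makes heme O, a precursor of the heme A in cytochrome c oxidase (respiratory complex IV). Its level was not lower. In hepatocyte-like nuclei it stood at 35.6 CPM (UMI counts scaled to the depth of the sum; 31.4 to 40.3, 253 UMIs) in the wild-type library and at 43.1 CPM (37.0 to 49.9, 178 UMIs) in the Cox10-/- library, a ratio of 1.21 (0.994 to 1.47). Within the Cox10-/- library the level was 44.9 CPM in endothelial-like and 28.5 CPM in stellate-like nuclei, so hepatocyte-like nuclei were not set apart. Cox10 (ENSMUSG00000042148.8) lies on chromosome 11, from 63962627 to 64079468 on the minus strand of mm10. The labels name neither the floxed exon nor the virus given to each animal, and a 3' tag outside a deleted exon would not show its loss, so these counts cannot check the deletion. The ratio fell below 1 when every nucleus counted alike, at a log2 of -0.19 after thinning each nucleus to 1000 UMIs and -0.17 for the mean over nuclei.

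The second comparison covered the makeup of the 2 preparations. Hepatocyte-like nuclei made up 97.3% of the wild-type library (96.3 to 98.0, 1500 of 1542 nuclei kept) and 37.1% of the Cox10-/- library (35.4 to 38.8, 1160 of 3128). Endothelial-like nuclei, marked by Stab2, Ptprb and F8, were 627 of 3128 nuclei of the Cox10-/- library (18.7 to 21.5%), against 0 of 1542 wild-type nuclei. The 0 rests on the naming rule, since an unnamed cluster led by Bmp6, Egfl7 and Ptprb held 25 wild-type and 207 Cox10-/- nuclei, and with it the endothelial shares were 1.62% (1.05 to 2.38) and 26.7% (25.1 to 28.2). Stellate-like nuclei, from the vitamin A-storing pericytes of the liver, were 19.7% (18.3 to 21.2) against 0.13% (0.0157 to 0.468). Myeloid-like nuclei were 8.79% (7.82 to 9.84) against 0.195% (0.0401 to 0.568), and lymphoid-like nuclei 2.24% (1.75 to 2.82) against 0.584% (0.267 to 1.11). The lymphoid-like cluster was mixed, led by Siglech, a dendritic marker counted here as myeloid, as well as by Skap1 and Themis. At a resolution of 2.0, 13 Cox10-/- nuclei led by Siglech formed a separate myeloid-like cluster. Cholangiocyte-like nuclei, from bile duct epithelium, were 0.735% (0.467 to 1.10) against 0.13% (0.0157 to 0.468). Unnamed clusters held 11.4% (10.3 to 12.5) of the Cox10-/- and 1.69% (1.10 to 2.46) of the wild-type nuclei. Such shares also reflect perfusion, digestion and straining, which were done per animal. The Cox10-/- hepatocyte share was 21.9% when a shallow cluster described below was not counted as hepatocyte-like but stayed in the total of 3128 nuclei. It was 22.8% without the highest 4% of doublet scores and 24.4% at a Leiden resolution of 2.0, settings in which 472 and 408 of these shallow nuclei went unnamed.

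**Figure D1:**
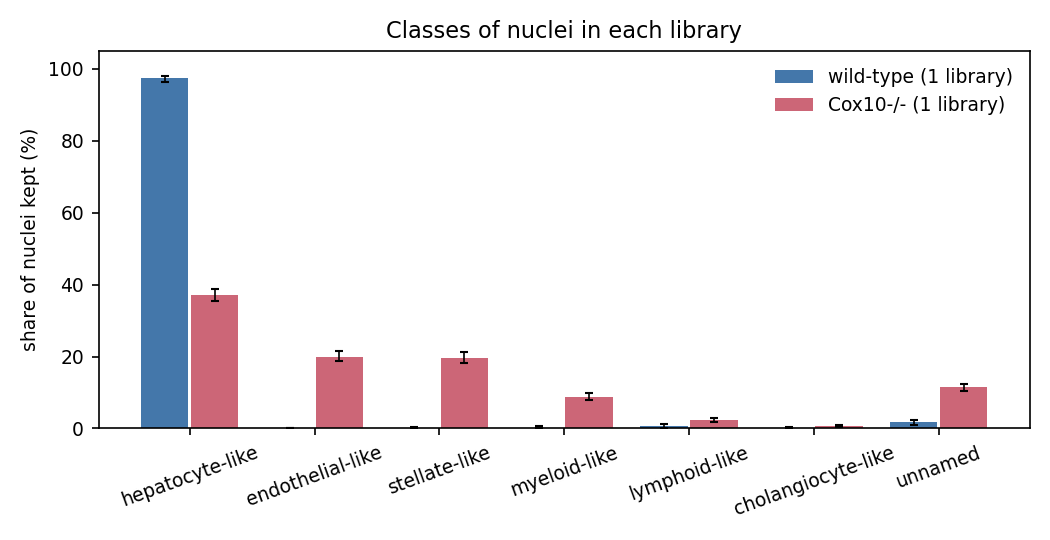
Share of nuclei in each named class (percent of nuclei kept) in the wild-type and Cox10-/- libraries, with exact 95% counting intervals. Hepatocyte-like nuclei stood at 97.3% in the wild-type and 37.1% in the Cox10-/- library, and endothelial-like nuclei at 0 of 1542 and 627 of 3128, without an unnamed cluster with endothelial markers that held 25 and 207 nuclei.

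Hepatocyte-like nuclei of the 2 libraries fell into different clusters. The libraries were clustered together without integration, so genotype and preparation cannot be told apart in this split. Wild-type nuclei filled 3 clusters of 675, 541 and 281 wild-type nuclei, of which the last was led by Cyp7a1, Cyp2c38 and Slc1a2. The main Cox10-/- cluster held 620 Cox10-/- and 3 wild-type nuclei and was led by Scara5, Cyp2b10 and Etnppl. A cluster of 57 Cox10-/- nuclei was led by Meg3, Rian, Slc1a2, Lgr5 and Glul. Another group of 476 Cox10-/- nuclei was shallow, with a median of 1136.5 UMIs, and was led by the acute phase and plasma protein genes Saa1, Hpx and Hp. In this shallow cluster 13 hepatocyte marker transcripts stood 2.28 to 3.77 times above their level in the non-hepatocyte nuclei of the same library. In the deeper Cox10-/- hepatocyte-like nuclei the same ratios ran from 0.603 for Serpina1c to 6.11 for Cps1, the first enzyme of the urea cycle.

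**Figure D2:**
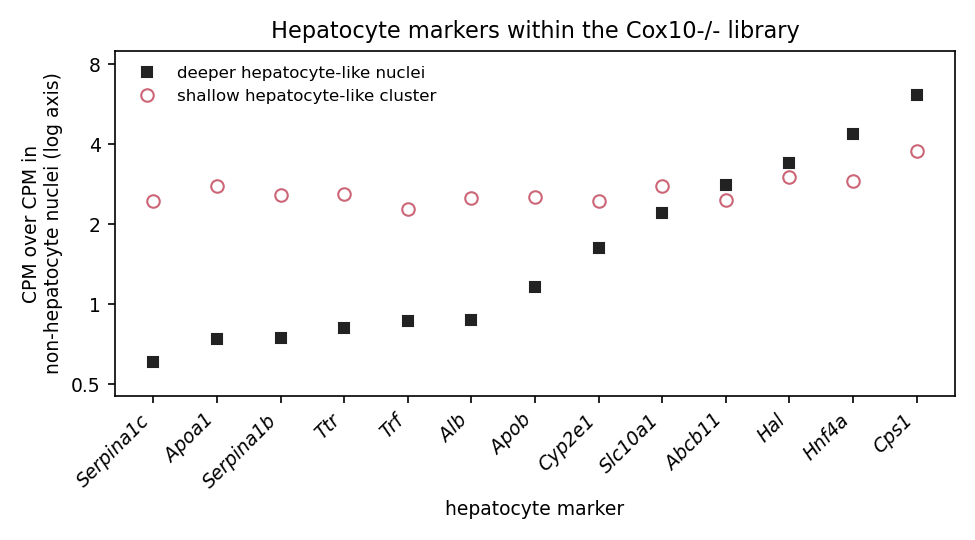
CPM of 13 hepatocyte marker genes in Cox10-/- hepatocyte-like nuclei divided by their CPM in the other named nuclei of that library (log axis), for the shallow cluster and for the deeper nuclei. The shallow cluster lies between 2.28 and 3.77 for every marker, while the deeper nuclei range from 0.603 to 6.11.

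The third comparison, the main one, set the summed hepatocyte-like nuclei of the 2 libraries against each other, with 7106783 UMIs in the wild-type and 4127716 in the Cox10-/- sum. Cyp2b10, a drug-metabolising cytochrome P450 under the receptor CAR, stood at 0.281 CPM in the wild-type and 65.9 CPM in the Cox10-/- library, 234-fold higher (64.2 to 1943). The related Cyp2c39 was 60.0-fold higher (37.6 to 102). The imprinted noncoding RNAs Meg3 and Rian are neighbours on chromosome 12 (starting at 109541001 and 109603940). Meg3 was 72.3-fold higher (46.5 to 119). Rian had 0 wild-type UMIs and was 98.7-fold higher against the floor of 3 UMIs over the wild-type library, with a counting interval from 79.4-fold. Col4a3, a basement membrane collagen, was 29.99-fold higher (16.8 to 59.0), and the immediate early gene Fosb 86.1-fold (23.2 to 721). Lower in the Cox10-/- library were Hsd3b5, a male-biased steroid dehydrogenase (41.4-fold, 13.99 to 202), Cyp17a1, a steroid hydroxylase (24.3-fold, 9.30 to 90.0), and Sntg1, a syntrophin (14.8-fold, 11.0 to 20.3). Also lower were Onecut1, a hepatocyte transcription factor (6.66-fold, 5.61 to 7.96), Hacl1, a peroxisomal enzyme of fatty acid alpha-oxidation (6.26-fold, 5.66 to 6.94), and Cyp4a14, a target of PPAR-alpha (9.64-fold, 5.11 to 20.5).

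The other genes at the top of the ranking were Gldn, Gstp3, Saa1, Saa2, Cyp3a11, Osbpl3, Cd74 and Dcn, with ratios from 18.6 for Cyp3a11 (16.6 to 21.0) to 164 for Gldn (28.7 to 6528). Of these, Cd74, an antigen presentation gene, and Dcn, a matrix gene of stellate cells, belong to other cell types. Gstp3, Saa1, Saa2, Cyp3a11, Osbpl3, Cd74 and Dcn did not exceed their level in the non-hepatocyte nuclei by the factor of 2 used here to set a gene above free RNA. At the other end stood Srgap3, Trhde, Gna14, Prex2, Fras1, Cacna1d, Pclo and Cables1, lower by 8.97-fold for Cacna1d (5.98 to 14.03) to 49.95-fold for Srgap3 (13.6 to 416). Of the 14 lowest genes only Cyp17a1, Cacna1d and Cyp4a14 were above free RNA. For lower genes the reference was the other wild-type nuclei. These held Onecut1 at 184.9 CPM and Hacl1 at 358.5 CPM, against 230.8 and 628.3 CPM in wild-type hepatocyte-like nuclei. Here and in the lists below, failing the rule thus does not show that a lower level came from free RNA. Since higher and lower genes met different references, a median over only the genes above free RNA depends on direction. It does not correct the median of the whole list. Among 11424 genes with at least 20 UMIs, 865 were at least 2-fold higher in the Cox10-/- library and 372 at least 2-fold lower, with the whole counting interval beyond 1.5-fold. Leaving out the shallow cluster gave 541 higher and 333 lower genes, of which 505 and 311 were also counted with it. The number of higher genes was 539 with at least 100 UMIs per gene, 546 without the highest 4% of doublet scores, where the shallow nuclei went unnamed, and 1501 for the mean over nuclei, and 144 genes were higher and 108 lower among the 1738 above free RNA.

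Transcripts of the respiratory chain split by genome of origin. Here and in the lists that follow, a gene counts as higher or lower from a ratio of 1.5. All 12 measured nuclear-encoded subunits of complex IV were higher in the Cox10-/- library, with a median log2 ratio of 1.07. Cox4i1 stood at 102 and 242 CPM (2.38-fold, 2.16 to 2.62), and Ndufa4 was 2.84-fold higher (2.51 to 3.22). Of 36 complex I subunits 27 were higher and none was lower (median 0.88), with Ndufc2 3.23-fold higher (2.501 to 4.18), and of 29 subunits of complexes II, III and V 21 were higher and none lower (median 0.94), with Atp5g3, of ATP synthase, 3.07-fold higher (2.73 to 3.46). Among 22 assembly factors of complex IV only 5 were higher, among them Coa3 and Cox17, and 1 was lower (median 0.29). Of the 13 mitochondrially encoded transcripts 11 were lower and none higher (median -1.03), with mt-Nd3 at 1919 and 607 CPM (3.16-fold lower, 3.03 to 3.30) and mt-Atp8 3.15-fold lower (2.88 to 3.44). In a nuclear preparation these transcripts reflect cytoplasmic carry-over. Nuclei above 10% of such UMIs, 71.7% of wild-type and 39.3% of Cox10-/- nuclei, had been left out, which affects the size of this difference. In all deposited nuclei the median share of these UMIs was 12.6% in wild-type and 8.17% in Cox10-/- hepatocyte-like nuclei.

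Beside these, 33 of 35 cytoplasmic ribosomal protein transcripts, fixed as a check on cytoplasmic RNA carried along with nuclei, were higher, with a median of 1.47 and Rplp1 3.90-fold higher (3.52 to 4.33). Without the shallow cluster 7 of 12 complex IV subunits, 10 of 36 complex I subunits and 10 of 29 subunits of complexes II, III and V were higher. The medians were then 0.84 for ribosomal proteins, 0.66 for complex IV, 0.38 for complex I, 0.33 for complexes II, III and V and -1.31 for the mitochondrially encoded transcripts. Except for 4 assembly factors of complex IV, no gene of these respiratory and ribosomal lists was above free RNA. Genes expressed at similar levels in all classes cannot meet this rule. Cox4i1, for example, stood at 242 CPM in hepatocyte-like and 304 CPM in other Cox10-/- nuclei. Failing the rule therefore does not show that these transcripts were free RNA. Among 10000 random lists matched on expression, the medians of ribosomal proteins, complex IV, complex I and complexes II, III and V lay at percentile 100 and that of the mitochondrially encoded transcripts at percentile 0. With matching on exon length as well, complex IV lay at percentile 95.4.

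The stress lists differed among themselves in hepatocyte-like nuclei. Of 23 measured genes of the integrated stress response, the program run by ATF4, 12 were higher and 1 lower (median 0.64), but only 4 were above free RNA, with Atf3, Cebpb and Cth higher and Mthfd2 lower. Atf3, a stress-induced transcription factor, stood at 46.7 and 214 CPM (4.58-fold, 4.03 to 5.21), and the mTORC1 inhibitor Ddit4 was 8.20-fold higher (4.82 to 14.8). Nupr1, with 0 wild-type UMIs, was 21.2-fold higher against the floor, with a counting interval from 16.4-fold. Of 17 genes of p53 signalling and cell cycle arrest 10 were higher and 1 lower (median 0.77), and of the 5 above free RNA Btg2, Trp53inp1, Plk3 and Ei24 were higher and none lower. Named members were Btg2 3.595-fold (3.34 to 3.88), Trp53inp1 3.17-fold (2.93 to 3.42) and the cyclin-dependent kinase inhibitor Cdkn1a 8.95-fold higher (3.38 to 29.9). Ddit4, Nupr1 and Cdkn1a were not above free RNA. The Nupr1 reference (19.98 CPM) however exceeded every named non-hepatocyte class of the main setting (at most 8.93 CPM). Of 13 targets of NRF2, the regulator of antioxidant genes, 10 were higher and none lower (median 1.15), although none was above free RNA. Among 14 mitochondrial chaperones and proteases 5 were higher and none lower (median 0.31), with Hspa9 1.98-fold (1.79 to 2.18) and Lonp1 2.05-fold higher (1.57 to 2.68), and 2 were higher without the shallow cluster. No member of this list was above free RNA. The hypoxia list had 3 of 12 genes higher and 1 lower (median -0.10), and the interferon list 3 of 10 higher and 1 lower (median 0.09).

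Immediate early and heat shock genes, fixed as a check on tissue handling, pointed in the same direction as the integrated stress response, p53 and NRF2 lists. Of 14 measured members 13 were higher and none lower (median 1.28), with Fos 6.30-fold (5.08 to 7.86) and Ier2 3.28-fold higher (2.97 to 3.62). Of the 10 members above free RNA 9 were higher. The integrated stress response, p53, NRF2 and handling medians lay at percentile 100 of random lists, and without the shallow cluster they were 0.57, 0.69, 0.78 and 1.25. Btg2 belongs to both the p53 and the handling list.

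Genes of fuel use went several ways. Of 18 genes of glycolysis and lactate 11 were higher and 2 lower (median 0.95, or 0.60 without the shallow cluster), with Gpi1, glucose-6-phosphate isomerase, 3.36-fold higher (2.96 to 3.81). Only 5 were above free RNA, Gpi1 among them, with a median of 0.53. Gluconeogenesis had 4 of 10 genes higher and none lower (median 0.48). Its last enzyme, the glucose-6-phosphatase G6pc, stood at 1001 and 2479 CPM (2.48-fold, 2.40 to 2.55). Among 30 genes of fatty acid oxidation and PPAR-alpha 3 were higher and 7 lower (median -0.08), with Cyp4a10 at 92.0 and 20.4 CPM (4.52-fold lower, 3.599 to 5.74) and the acyl-CoA synthetase Acsl1 2.31-fold lower (2.21 to 2.40). Pdk4, the kinase that shuts pyruvate out of the TCA cycle, was 5.34-fold higher (3.18 to 9.33) but not above free RNA. The reference included a cluster with Pdk4 among its leading genes, so for Pdk4 it does not measure free RNA alone. The lists for pyruvate dehydrogenase (3 of 12 higher, 1 lower), the TCA cycle (3 of 14 higher, none lower) and mitochondrial biogenesis and mitophagy (2 of 18 higher, 2 lower) had medians of -0.12, 0.14 and -0.09. In the last of these the coactivator Ppargc1a was 1.87-fold higher (1.78 to 1.98).

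Cholesterol synthesis genes were lower or within 1.5-fold. Of 20 genes of cholesterol synthesis 11 were lower and none higher, with a median of -0.64 at percentile 0 of random lists, but only 2 were above free RNA. Fdft1, squalene synthase, stood at 108 and 35.4 CPM (3.06-fold lower, 2.56 to 3.68), and Msmo1 was 2.53-fold lower (2.20 to 2.92), neither above free RNA. In the bile acid list 4 of 16 genes were lower and 3 higher (median -0.28), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 2.83-fold (2.39 to 3.35), Cyp7b1 3.56-fold (3.26 to 3.90) and the uptake transporter Slco1a1 4.29-fold lower (3.94 to 4.68). These 3 were not above free RNA, and the 6 members above it, none of them lower, had a median of -0.04. Lipogenesis had 5 of 17 genes higher and 4 lower (median 0.22), with Acly, ATP citrate lyase, 2.26-fold higher (2.11 to 2.43) and Acacb, an acetyl-CoA carboxylase, 2.71-fold lower (2.43 to 3.02). Acacb was not above free RNA, and the 9 members above it, none of them lower, had a median of 0.53. Among 13 genes of lipid droplets and uptake 6 were higher and 1 lower (median 0.40), with the droplet coat gene Plin5 2.66-fold higher (2.19 to 3.24). The urea cycle list had 1 of 8 genes higher and none lower (median 0.14), and that gene, the mitochondrial ornithine carrier Slc25a15, was 3.79-fold higher (3.52 to 4.08). Above free RNA the medians were 0.92 for 3 genes of lipid droplets and uptake, 0.21 for 7 of the urea cycle, 0.40 for 9 of gluconeogenesis and -0.19 for 6 of fatty acid oxidation.

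Zonation and identity genes differed as well. Of 17 pericentral genes, active around the central vein, 12 were higher and 1 lower (median 1.36, percentile 100), with the Wnt pathway receptor Lgr5 at 9.43 and 39.2 CPM (4.16-fold, 3.11 to 5.62) and Lect2, which was not above free RNA, 6.59-fold higher (4.51 to 9.86). Only 6 pericentral genes were above free RNA, with a median of 0.71, of which Lgr5, Ahr and Slc1a2 were higher and none lower. Of 17 periportal genes 7 were higher and 1 lower (median 0.27), with Etnppl 3.98-fold higher (3.67 to 4.31). Xenobiotic metabolism had 7 of 17 genes higher and 2 lower (median 0.36), and the hepatocyte transcription factors 1 of 16 higher, the estrogen receptor Esr1 (1.69-fold, 1.55 to 1.86), and 3 lower, namely Onecut1, Foxa2 and Foxa1 (median -0.22). These 3 were not above free RNA. Over the 4 factors above it, none of them lower, the median was 0.19. It was 0.41 for 8 periportal and 0.36 for 8 xenobiotic genes above free RNA. Acute phase genes, which the liver makes in inflammation, had 14 of 24 higher and 1 lower, with a median of 1.01 that was 0.60 without the shallow cluster. Of the 4 above free RNA Orm3, Saa3 and Hamp were higher and Socs3 was lower. Saa1 was 38.5-fold higher (25.1 to 62.0) with the shallow cluster and 23.3-fold without it, and Saa2 45.01-fold (21.4 to 113.5) and 29.4-fold.

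Fetal and progenitor genes had 6 of 9 measured members higher and 2 lower (median 0.74), with H19 43.0-fold (7.05 to 1767, 1 wild-type UMI) and the bile duct gene Spp1 15.5-fold higher (7.77 to 35.1), or 8.07-fold without the shallow cluster. No member was above free RNA, and the median turned to -0.74 after thinning and to -0.54 with at least 100 UMIs per gene. Genes more active in male liver had 8 of 12 members lower and 3 higher (median -0.98, percentile 0), with Elovl3 12.5-fold lower (3.25 to 106) and Cyp4a12b 6.39-fold lower (2.96 to 16.4), neither above free RNA, and Elovl3 had 0 Cox10-/- UMIs without the shallow cluster. The 2 members above free RNA, Selenbp2 and Cyp2u1, were lower. Of 3 female-biased genes 2 were higher and 1, Cyp17a1, was lower (median 0.87). Of 5 sex chromosome genes 1, Tsix, was lower (15.4-fold, 4.06 to 130) and none was higher (median 0.01), and the Y-linked Uty stood at 320 and 328 CPM. Of 5 nuclear retained RNAs 1, Meg3, was higher and none lower (median 0.03), with Malat1 at 22310 and 18730 CPM.

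The lists for inflammation (4 of 5 higher, 1 lower, median 1.38), stellate matrix (3 of 4 higher, none lower, median 1.99) and endothelial signals (3 of 4 higher, none lower, median 1.82) had few measured genes in hepatocyte-like nuclei. Of these 13 measurements only the neutrophil attractant Cxcl1 (2.60-fold higher, 2.16 to 3.14) and the fibronectin gene Fn1 were above free RNA. Fn1 was neither higher nor lower, at a log2 ratio of 0.13. With at least 1000 genes per nucleus the endothelial median turned to -0.13. In total 16 of the 40 lists had a median at least 1.5-fold higher and 3 a median at least 1.5-fold lower.

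**Figure D3:**
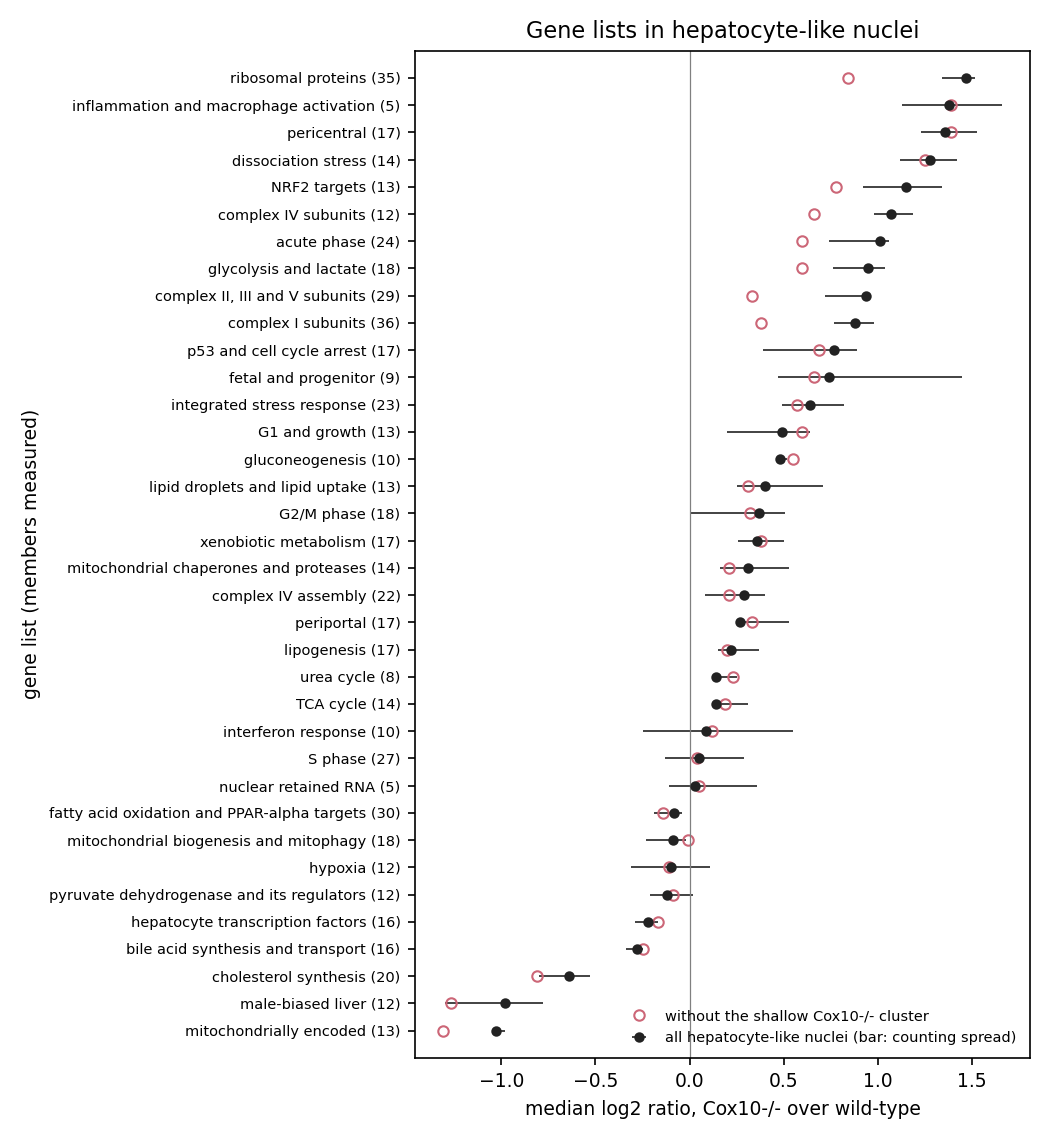
Median log2 ratio of Cox10-/- over wild-type CPM in hepatocyte-like nuclei for lists with at least 5 measured genes other than the sex chromosome list, with all nuclei (bars, counting spread over 200 Poisson draws) and without the shallow cluster. Pericentral (1.36), ribosomal protein (1.47) and handling stress (1.28) lists lie to the right, and mitochondrially encoded (-1.03), male-biased (-0.98) and cholesterol synthesis (-0.64) lists to the left.

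The fourth comparison asked how many hepatocyte-like nuclei carried cell cycle transcripts. After thinning to 1000 UMIs, 9.68% of Cox10-/- nuclei (8.01 to 11.6, 108 of 1116) and 7.34% of wild-type nuclei (6.07 to 8.78, 110 of 1499) had at least 2 UMIs over the G2/M list, a ratio of 1.32 (1.0 to 1.74). For the S phase list the shares were 4.84% (3.66 to 6.27) and 4.14% (3.19 to 5.27), a ratio of 1.17 (0.797 to 1.71). In the Cox10-/- library 8.91% of stellate-like (6.79 to 11.4), 12.5% of myeloid-like (8.85 to 17.1) and 32.9% of lymphoid-like nuclei (22.1 to 45.1) passed the G2/M limit, so the hepatocyte share lay at the level of stellate-like nuclei and no cycling is read from that share. A small hepatocyte-like cluster led by Diaph3, Cenpp and Cep128, not separate in the main setting, held 3 wild-type and 10 Cox10-/- nuclei at a resolution of 2.0. It held 3 and 9 with at least 1000 genes, 4 and 10 with no filter and 2 and 9 without the highest 4% of doublet scores. Mki67, a proliferation marker, had 2 wild-type and 13 Cox10-/- UMIs, and the topoisomerase gene Top2a had 0 and 15. With thinning, the alternatives gave ratios of 1.20 to 1.60 for G2/M and 0.884 to 1.31 (1.01 to 1.69, at 2000 UMIs) for S phase. Without thinning, where deeper nuclei pass more often, the ratios turned to 0.765 for G2/M and 0.651 for S phase. With the shallow cluster left out as well they did not turn, at 67.7% of Cox10-/- and 58.9% of wild-type nuclei for G2/M and 41.8% and 41.3% for S phase.

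By gene, 6 of 18 G2/M genes were higher and 1 lower (median 0.37), with the mitotic kinase Cdk1 18.1-fold higher (4.42 to 159). Of 27 S phase genes 5 were higher and 2 lower (median 0.05), with E2f8, a repressor of E2F targets linked to polyploidy, 8.36-fold lower (3.42 to 26.5). Of 13 genes of G1 and growth 6 were higher and none lower (median 0.49), with cyclin D1 (Ccnd1) at 3.38 and 34.9 CPM (10.3-fold, 6.67 to 16.7) and Ccn1, a target of the growth regulator YAP, 5.44-fold higher (4.30 to 6.94). None of Cdk1, E2f8, Ccnd1 and Ccn1 was above free RNA.

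The fifth comparison, of gene lists in other cell classes, was not possible as planned, since 0 other classes had at least 100 nuclei in both libraries. In all deposited nuclei, with a minimum of 30 nuclei chosen after seeing the data, 3 classes could be set side by side, at 44 and 1412 endothelial-like, 33 and 748 stellate-like and 47 and 741 myeloid-like nuclei in the wild-type and Cox10-/- libraries. The wild-type ones may hold hepatocyte RNA, with Onecut1 at 233 CPM in stellate-like and 232 CPM in hepatocyte-like nuclei. Their median mitochondrially encoded shares were 17.8%, 13.7% and 16.9%, against 9.29%, 7.02% and 12.2% in the Cox10-/- library. Differences in these classes may thus partly repeat those of hepatocyte-like nuclei. Over genes whose level in the class exceeded that in hepatocyte-like nuclei, ribosomal proteins had medians of 0.89, 1.17 and 1.27 in these classes and the mitochondrially encoded transcripts -0.89, -0.81 and -0.40. Complex I subunits had medians of 1.02, -0.17 and 0.65, and over all 36 measured genes 1.02, 0.59 and 1.15, so the stellate sign depends on the rule. Complex IV subunits, with too few such genes in stellate-like nuclei, had medians of 1.33 in endothelial-like and 1.15 in myeloid-like nuclei, where 5 of 7 and 6 of 8 NRF2 targets were higher and none lower. Over all measured genes the medians were 0.90, 1.25 and 1.24 for ribosomal proteins, 1.36, 1.33 and 1.13 for complex IV and 1.04, 1.30 and 1.29 for NRF2 targets, of which 8 of 12, 6 of 10 and 10 of 13 were higher and 1, 0 and 0 lower. The integrated stress response had medians of 0.23, -0.79 and -0.09 under this rule and of 0.55 (0.32 to 4.79), 0.21 (-0.23 to 2.13) and 0.45 (0.09 to 1.43) over all measured genes, so 2 of its 3 signs depend on the rule. Too few handling stress genes met the rule, and over all 11 measured ones 9 were higher in endothelial-like, 5 in stellate-like and 6 in myeloid-like nuclei and 0, 2 and 0 lower, with medians of 1.29 (0.81 to 2.40), 0.20 (-0.14 to 0.98) and 0.78 (0.20 to 1.31).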

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

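All tests of explanations in this part were chosen only after the result was seen, except that of carry-over common to the whole Cox10-/- library. Dendra2, a photoconvertible fluorescent protein that is not a mouse gene and is not mentioned in the labels, has a row in the table and was used in no comparison. It stood at 413 CPM in Cox10-/- and 200 CPM in wild-type hepatocyte-like nuclei, 2.07-fold higher (1.93 to 2.22).

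The hepatocyte-like share was 97.3% in the wild-type and 37.1% in the Cox10-/- library. The mitochondrial limit as the source is argued against, since without it the shares still differed by 61.4 percentage points. A loss of hepatocyte nuclei alone, which would raise every other class by 1 factor, stays open. In all deposited nuclei the lymphoid ratio lay at most at 12.1 and the endothelial ratio at least at 25.1, but these bounds leave out the spread between animals, and with an unnamed endothelial-marked cluster the endothelial ratio was 10.9 (9.14 to 13.1), still beside 24.0 (16.9 to 35.1) for stellate-like and 7.14 (4.44 to 12.1) for lymphoid-like nuclei. Genotype, animal, perfusion, digestion, the authors' filter and library are confounded in 1 library per group, so a biological difference between wild-type and Cox10-/- liver is untested.

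The shallow cluster of 476 Cox10-/- nuclei may be droplets that hold free hepatocyte RNA without a whole hepatocyte nucleus. Free RNA keeps its genes in 1 ratio, and over 13 hepatocyte markers the log2 ratio of this cluster to the other nuclei had an SD of 0.187 (0.175 to 0.246), against 1.12 (1.09 to 1.14) in the deeper hepatocyte-like nuclei. Alb, the most abundant marker, stood at 36810 CPM in this cluster, against 12690 CPM in the deeper and 14580 CPM in the other nuclei. Malat1, a nuclear RNA, stood at 6835 CPM there, against 18730 CPM over all Cox10-/- hepatocyte-like nuclei. The shallow cluster was set apart by its low Malat1, so this value follows from the selection and cannot test the free RNA reading. Damaged hepatocyte nuclei or cytoplasm attached to nuclei remain open, and no biological explanation was tested.

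The lists of nuclear-encoded respiratory subunits and of ribosomal proteins had higher medians in Cox10-/- hepatocyte-like nuclei, whereas mitochondrially encoded transcripts were lower. The shallow cluster as the whole source is argued against, since without it the lowest of the medians of ribosomal proteins and of complexes I, IV and II, III and V, that of the last list, was still 0.33 (0.32 to 0.51). This range comes from Poisson redraws that lay mostly above the value, so its lower end is not an exact bound. Exon length as the source is argued against for ribosomal proteins and complex I, at percentile 100 of lists matched on it. Complex IV, at percentile 95.4, lay between the limits set and stays undecided. The match used all annotated exons of a gene, not transcript length or intron content, so short transcripts in general stay open. Cytoplasmic RNA carried over in the whole Cox10-/- library stays open as a source. Ribosomal proteins were also higher in its other classes, with the lowest median in endothelial-like nuclei at 0.90 over all measured genes (0.63 to 1.29). Mitochondrially encoded transcripts were however lower there, and only 33 to 47 wild-type nuclei per class enter. These may hold hepatocyte RNA, with Onecut1 at 233 CPM in wild-type stellate-like and 232 CPM in wild-type hepatocyte-like nuclei. The comparison may thus repeat that of hepatocyte-like nuclei and cannot show carry-over in every class. A response of the respiratory genes to the genotype is untested and stays open.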

How the results depend on the processing

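Alternatives without the shallow cluster, without the highest 4% of doublet scores, with genes above free RNA and with unnamed clusters counted under their lineage were chosen only after the result was seen. No paired analysis was possible because each group holds 1 library from 1 animal. The limit of 1% mitochondrially encoded UMIs gave no value, with 0 wild-type and 10 Cox10-/- nuclei left. The log2 ratio of Cox10 lay between 0.17 and 0.45 under 11 alternatives and turned to -0.19 after thinning and -0.17 for the mean over nuclei, settings where the median of all genes was -0.12 and -0.11. The Cox10-/- hepatocyte share was 34.0% with no filter (wild-type 95.4%), 28.7% with at least 1000 genes, 24.4% at resolution 2.0 (408 shallow nuclei went unnamed) and 22.8% without the highest 4% of doublet scores (472 went unnamed). It was 21.9% with the shallow cluster not counted as hepatocyte-like but kept in the total. Endothelial shares with the unnamed cluster were 1.62% and 26.7%, of which the wild-type one rests on nuclei whose identity is open. Genes higher numbered 539 with at least 100 UMIs, 546 without the highest 4%, 541 without the shallow cluster, 1501 for the mean over nuclei and 144 above free RNA. Genes lower numbered 583 for the mean over nuclei and 108 above free RNA. Without thinning the cycling ratios were 0.765 (G2/M) and 0.651 (S), where depth differs between the libraries. The fetal list turned to -0.74 after thinning and -0.54 with at least 100 UMIs, and the endothelial list to -0.13 with at least 1000 genes. Neat1 turned to 0.03 with at least 1000 genes, 0.02 at resolution 2.0, 0.04 without the highest 4% and 0.05 without the shallow cluster. Except for the restrictions to fewer genes and nuclei, the cause was not tested. Named genes kept their value within counting error in 1844 cases, moved in 349 and turned in 4. List medians did so in 473, 152 and 3, and the numbers of lists higher or lower stayed within 1.5 times under all 16 alternatives run for them.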

Other observations

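No test of an explanation is given in this part, and its clusters and genes were chosen only after their values were seen. A cluster of 91 Cox10-/- nuclei and 1 wild-type nucleus was led by Nrg1 and left unnamed in the main setting. With no filter, Nrg1, Pdk4 and Areg were among the leading genes of a cholangiocyte-like cluster of 10 wild-type and 190 Cox10-/- nuclei. The Cox10-/- nuclei of the unnamed cluster had a median of 4877 UMIs, against 4457.5 in the deeper and 2620 in all Cox10-/- hepatocyte-like nuclei. Against the deeper Cox10-/- hepatocyte-like nuclei, 20 of 25 genes of the integrated stress response were higher (median log2 ratio 1.86), as were 12 of 18 p53 genes (1.39), 10 of 13 NRF2 targets (1.51) and 8 of 9 fetal and progenitor genes (2.23). The cystine transporter gene Slc7a11 stood at 448 CPM against 2.27 CPM, 197-fold higher (98.2 to 463). The EGF receptor ligand Areg stood at 496 CPM against 4.26 CPM, and Pdk4 at 944 CPM against 13.05 CPM. All 8 urea cycle genes were lower (median -2.38), as were 12 of 17 periportal (-2.21) and 9 of 10 gluconeogenesis genes (-2.06). Arg1 stood at 84.6 CPM against 1249 CPM and the serine dehydratase gene Sds at 44.5 CPM against 871 CPM. Handling stress genes had a median of -0.66 there. The bile duct genes Kcnma1 and Spp1 stood at 2.23 and 15.6 CPM, against 2828 and 1645 CPM in cholangiocyte-like nuclei. Both are leading genes of the cholangiocyte-like cluster, so their gap does not settle the class of the unnamed cluster. Over the full marker lists the log2 excess of the unnamed cluster was 0.87 for cholangiocyte, the highest of the other classes, and -0.34 for hepatocyte.

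In all deposited nuclei, myeloid-like nuclei of the Cox10-/- library held Pparg, a lipid-sensing nuclear receptor, at 251 CPM against 6.46 CPM in wild-type (1 UMI, 38.8-fold, 6.93 to 1535), and Rgs1 at 511 CPM against 38.8 CPM (13.2-fold, 6.03 to 36.0). Endothelial-like nuclei held the antigen presentation genes H2-D1 and B2m 4.33-fold (2.62 to 7.75) and 3.58-fold higher (2.52 to 5.27). The hepatocyte-like nuclei of the same setting held H2-D1 at 72.6 and 485 CPM and B2m at 215 and 952 CPM in the wild-type and Cox10-/- libraries. In stellate-like nuclei Sntg1 stood at 506 CPM in the wild-type and 5788 CPM in the Cox10-/- library (11.4-fold, 8.67 to 15.4), the opposite direction to hepatocyte-like nuclei. The wild-type stellate-like nuclei also held hepatocyte genes at or above their level in wild-type hepatocyte-like nuclei, with Onecut1 at 233 against 232 CPM and Cyp7a1 at 121 against 85.5 CPM, while Cox10-/- stellate-like nuclei held both at 5.86 CPM. The wild-type values rest on 44 endothelial-like, 33 stellate-like and 47 myeloid-like nuclei.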
